A study of Rattus norvegicus with 6 samples.

How the data were processed

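RNA was measured on one-colour Affymetrix arrays in cultures of rat adipose-derived stem cells (ADSCs), the stromal precursor cells of fat tissue that can become adipocytes. Per the labels, the cells came from the inguinal fat of 2-week-old female Wistar rats. There were 3 control arrays and 3 arrays of cells kept for 7 days in adipogenic medium, all 6 called biological replicates in the labels. Control cells grew with 10% fetal bovine serum. The adipogenic medium held 0.5 mM 3-isobutyl-1-methylxanthine (IBMX, which raises cAMP), 1 µM dexamethasone (a synthetic glucocorticoid), 5 µg/ml insulin and 20% serum, so serum differed between the groups together with the inducers. The time that control cells spent in culture is not given in the sources used here. Biotin-labelled cRNA was made from 6 µg of total RNA, per the labels' protocols.

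The deposited values are on the log2 scale and were made with RMA (background correction, quantile normalization and probe summary), per the submitters' processing notes. The RMA version is not given in the sources used here. That the scale is log2 was read from the values: the array medians lay between 5.64 and 5.73, and no array exceeded 13.55. RMA gives no detection call, so a low value is not a bound here, and the compression of low signals makes folds of dim genes too small. Quantile normalization also gives each array nearly the same distribution, so a change in total RNA per cell cannot be seen. Arrays have no read depth, and their number limits the precision.

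The table had 36685 features. The platform annotation gave 18511 of them 1 gene symbol, 575 several and 17599 none, and no gene was named from a feature with several symbols. Of the features with 1 symbol, 18394 matched the GRCr8 gene table by gene number and 117 did not, and 0 symbols changed in the match. That table was used for names and gene types only, and no coordinates are given because the build behind the arrays is not given in the sources used here. Features were reduced to 18166 genes by taking, for each symbol, the feature with the highest mean over the 6 arrays. This choice mattered for 291 genes with more than 1 feature. Noncoding features were the 416 whose gene is typed as noncoding.

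Induced and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior, two-sided), without a block for replicate number, leaving 4 residual degrees of freedom. The prior added 2.65 degrees of freedom for genes. P-values were adjusted by the Benjamini-Hochberg method over all features or all genes, and a gene was called changed at an adjusted p under 0.05. Log2 changes are given with the standard error of the fit (SE), and levels as mean ± SD. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so none is reported for single genes. The comparison tests the spread between these cultures. The labels do not say whether they came from separate animals.

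A total of 31 gene lists (586 genes, of which 501 were measured) were fixed before the data were examined, among them markers of other cell types. Each was tested with camera at a preset correlation between genes of 0.01, adjusted over the 31 lists. With a correlation estimated from the data, 0 of the 17 camera calls held, and with fry, which asks whether a list moves on balance one way without comparing it with other genes, the smallest adjusted p was 0.0559 and 0 lists were called. Member counts are given over all genes and adjusted over the list alone.

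The genes named in the text follow a rule that was also fixed before the data were examined: the 12 largest rises and 12 largest falls among called genes whose 3 induced values all lay on one side of the 3 control values, leaving out placeholder symbols, small RNAs and pseudogenes. For each list, up to 4 called members were added, or the 2 with the largest change where none was called. Pparg, Cebpa, Adipoq, Fabp4, Lpl, Plin1 and Dlk1 were always included, and up to 3 rising and 3 falling called noncoding features were added. Genes named outside this rule are said to be so.

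The fit was tested on simulated data for this comparison, with 200 of 18166 genes changed. Of 68 genes changed by 1 on the log2 scale 57.4% were called. Of 66 changed by 2, 89.4% were called, and of 66 changed by 4, 98.5%. There were 5 false calls among 17966 unchanged genes. These rates describe the simulated data only. In the real data 510 genes averaged at least 2-fold higher and 394 at least 2-fold lower, while 114 genes were called with a change of that size. With 1 array left out, real calls ranged from 2 to 557 genes. Whether the simulated rates hold for the real arrays was not tested. In a simulation of the list test, 2 of 2 shifted lists and 0 unshifted ones were called. Genes were drawn independently there, so it cannot show how often camera calls unshifted lists whose members move together. Correlations estimated from the data ran from -0.073 (mural cell markers) to 0.945 (respiratory chain).

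Alternatives tried were a second quantile normalization, centring on array medians, leaving out the dimmest features and genes (1 in 3 by mean value), a trended and robust prior, array weights, replicate number as a block, leaving out each array, averaging the features of a gene, estimated correlation, fry, and a test against a 2-fold change. In the comparison itself 0 arrays were left out. Plots were drawn with matplotlib 3.10.9.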

Results

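Gene expression was compared between 3 cultures of rat ADSCs and 3 cultures of the same cell type after 7 days of adipogenic induction, to ask which coding and noncoding genes differ once the cells are driven towards adipocytes. Values are log2 RMA signals, and every difference is induced minus control over 3 arrays per group. Array medians ranged from 5.64 to 5.73. The 3 control arrays correlated with each other across features at r = 0.9789 to 0.9852. Induced replicates 1 and 2 were closer still (r = 0.9894, with 546 features over 2-fold apart), while induced replicate 3 lay further off, 2745 and 2664 features being over 2-fold apart from induced replicates 1 and 2. Its r with them was 0.9681 and 0.9687. Pairs across the groups ran from r = 0.9478 to 0.9816, the highest being control replicate 1 with induced replicate 2. Each array correlated best with an array of its own group. Yet control replicate 1 correlated better with induced replicates 1 and 2 (r = 0.9793 and 0.9816) than induced replicate 3 did. The labels do not say whether induced replicates 1 and 2 share a culture or a day, and if they do, the standard errors and p-values here are too small. Correlations across features describe arrays, since features are not independent replicates.

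Genes for making and storing fat were among the largest rises in induced cells: 6 of 20 measured fatty acid and triglyceride synthesis genes and 5 of 17 lipid droplet and lipolysis genes passed, all higher. The largest rise was that of Thrsp, a regulator of lipogenesis, by 6.04 on the log2 scale (SE 0.61, adjusted p = 0.0186), from 6.73 ± 1.32 in control to 12.77 ± 0.28 in induced cells (SD, n = 3 arrays each). Pnpla3, a lipid droplet enzyme, rose by 5.36 (adjusted p = 0.0181). Agt, which encodes angiotensinogen, rose by 5.34 (SE 0.21, adjusted p = 0.000952), from 6.50 ± 0.41 to 11.83 ± 0.08 (SD, n = 3). Gpd1, which supplies glycerol phosphate for triglycerides, rose by 4.93, the retinol carrier Rbp4 by 4.77, the adipokine Retn by 4.72, and the lipid droplet genes Cidec and Cidea by 4.62 each. Akr1c15 rose by 4.37, Mtarc1 by 4.34, Apobec1 by 4.33 and the thyrotropin receptor Tshr by 4.31, with adjusted p from 0.0184 to 0.0481.

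The largest fall was that of Aspn, a small leucine-rich matrix proteoglycan, by 4.40 (SE 0.60, adjusted p = 0.0368), from 9.96 ± 1.21 to 5.55 ± 0.54 (SD, n = 3). Igsf10 fell by 3.25 (adjusted p = 0.00799), the amino acid transporter Slc38a4 by 2.81 and Vwa5al1 by 2.58. The collagen gene Col8a1 fell by 2.45 (adjusted p = 0.00799). Phlda1 fell by 2.27 and Itga11, a collagen-binding integrin, by 2.20. The inflammasome sensor Nlrp3 fell by 2.00, and the decoy interleukin 1 receptor Il1r2, the cell cycle phosphatase Cdkn3 and the BMP receptor Bmpr1b by 1.94 each. Fxyd6 fell by 1.93.

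**Figure D1:**
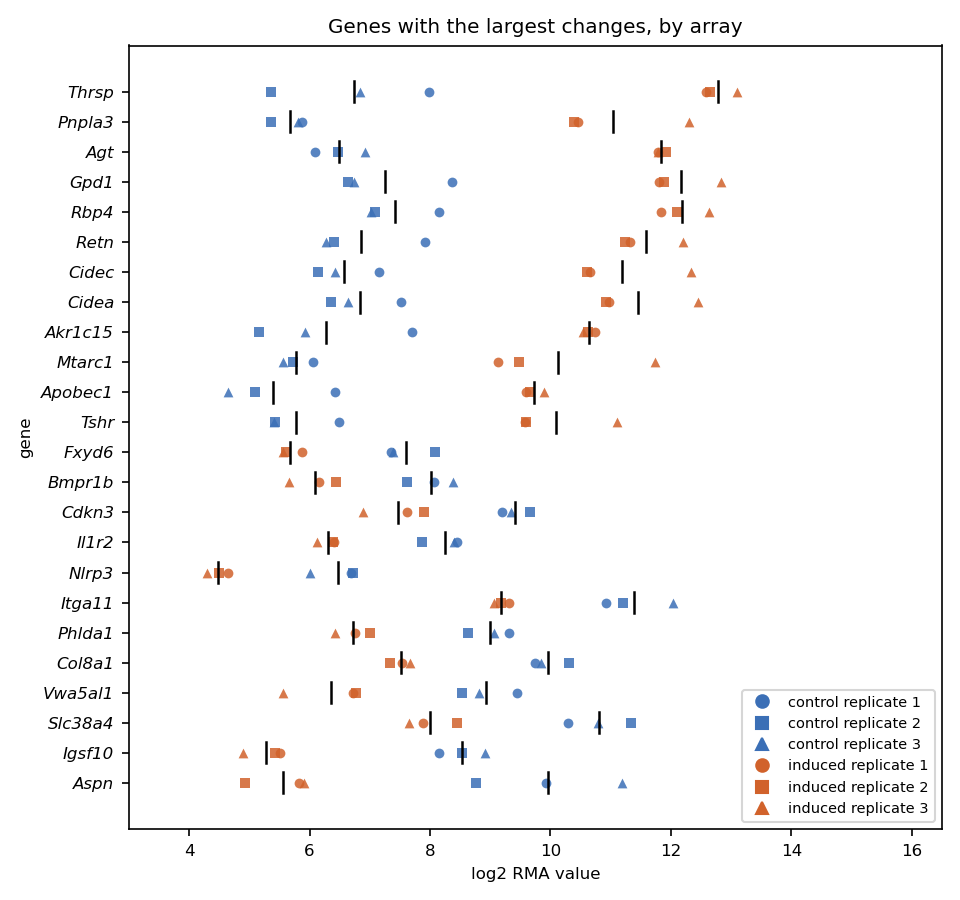
Log2 RMA value (horizontal axis) of the 12 genes with the largest rise and the 12 with the largest fall, 1 point per array, with the group means as black bars. Thrsp averaged 6.73 in control and 12.77 in induced cells, Aspn 9.96 and 5.55, and in each of the 24 genes the 3 induced arrays lie on one side of the 3 control arrays.

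In all, 136 of 18166 genes changed, 87 higher and 49 lower in induced cells, and 114 of them by 2-fold or more (77 higher, 37 lower). At an unadjusted p under 0.05 there were 3205 genes, and the 3 arrays of one group lay wholly above those of the other for 25.4% of genes, where chance gives 10%. Regardless of the test, 510 genes averaged at least 2-fold higher and 394 at least 2-fold lower, and 67 averaged at least 8-fold higher against 4 at least 8-fold lower. Over single features, 69 of 36685 changed (57 higher, 12 lower), among them 8 of the 17599 with no gene name here, all higher. Of the unnamed features 5087 are numbered below the first named one, and whether these are control probe sets is not known here. Without them 124 features changed (86 higher, 38 lower). The numbers depended on single arrays: 15 genes and 3 features changed without control replicate 2, 20 and 17 without control replicate 3, 2 and 2 without induced replicate 1, 26 and 2 without induced replicate 2, and 557 and 216 without induced replicate 3. The balance of directions depended on the fit too: 64.0% of changed genes were higher, against 51.0% of 929 with array weights and 56.2% of 740 without both replicate 3 arrays.

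Adipocyte genes moved together. All 23 measured mature adipocyte markers had positive estimates, with a median log2 change of 3.33. Of these, 11 rose over all genes tested and 21 adjusted over the list alone, and camera placed the list above other genes (adjusted p = 3.04e-25, and adjusted p = 0.435 with an estimated correlation). Thrsp, Gpd1, Rbp4 and Retn led it. Plin1, the coat protein of lipid droplets, rose by 4.28 (SE 0.53, adjusted p = 0.0312). Other well-known markers had large estimates that did not pass over all genes: Fabp4, a fatty acid carrier, at 4.25 (SE 0.65, adjusted p = 0.0507), the adipokine Adipoq at 3.93 (SE 0.78, adjusted p = 0.0866) and the lipase Lpl at 1.70 (SE 0.40, adjusted p = 0.113). In control replicate 1 these genes lay above the other control arrays: Adipoq read 10.04 there against 7.62 and 6.98, and Fabp4 read 9.80 against 7.23 and 7.63. The mean of the whole list was 8.25 on control replicate 1, 7.01 and 6.97 on the other control arrays, and 10.41, 10.37 and 11.60 on the induced arrays.

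Among the adipogenic transcription regulators, 0 of 15 measured genes passed over all genes, while adjusted over the list alone 6 rose and 2 fell. The list as a whole was higher by camera (median 0.63, adjusted p = 0.00107, and adjusted p = 0.435 with an estimated correlation). Pparg, the master regulator of adipogenesis, had an estimate of 3.67 (SE 0.62, adjusted p = 0.065), from 6.91 ± 1.13 to 10.58 ± 0.79 (SD, n = 3), and Cebpa one of 2.61 (adjusted p = 0.0762). Control replicate 1 was again the highest control array for both, at 8.17 and 8.19. Of 17 inhibitors of adipogenesis 1 passed over all genes, Dlk1, which rose by 1.02 (SE 0.13, adjusted p = 0.033). Adjusted over the list alone 1 rose and 1 fell, the latter being Tgfb1 (outside the naming rule), which stood at -0.93 (adjusted p = 0.053 over all genes). Dlk1 is known as a preadipocyte factor that holds back differentiation. The list did not shift (median -0.18, adjusted p = 0.567).

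Fat synthesis and storage genes were higher, but both lists share called genes with the mature adipocyte markers. These are Thrsp, Agpat2 and Dgat2 in the synthesis list and Plin1, Cidec and Pnpla2 in the droplet list. Agpat2, Dgat2 and Pnpla2 lie outside the naming rule. The lists are therefore not separate lines of evidence. In fatty acid and triglyceride synthesis 6 of 20 genes rose, 14 adjusted over the list alone, with a median of 1.99 (camera adjusted p = 1.13e-13, and adjusted p = 0.435 with an estimated correlation). Besides Thrsp they included Lpin1, a phosphatidate phosphatase, by 3.40, Scd, the desaturase that makes oleate, by 3.38 (adjusted p = 0.0115), and malic enzyme Me1, a source of NADPH, by 3.31. Of 17 genes for lipid droplet proteins and lipolysis 5 rose, 12 adjusted over the list alone, led by Pnpla3, Cidec, Cidea and Plin1, with a median of 2.74 (adjusted p = 2.37e-10, and adjusted p = 0.435 with an estimated correlation). Induced replicate 3 had the highest mean of both lists, 11.72 against 10.54 and 10.41 for synthesis and 10.10 against 9.04 and 8.92 for droplets.

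Mitochondrial genes were higher as groups, and more so on 1 array. In fatty acid oxidation 0 of 21 genes passed, also adjusted over the list alone, while 20 had positive estimates with a median of 1.30 (camera adjusted p = 6.49e-08, and adjusted p = 0.435 with an estimated correlation). Acaa2 stood at 1.93 (adjusted p = 0.182) and Hadh at 1.86 (adjusted p = 0.126). All 24 respiratory chain genes had positive estimates, median 0.84, and 0 passed by either adjustment (camera adjusted p = 1.63e-10, and adjusted p = 0.435 with an estimated correlation). Sdha and Cyc1 stood at 1.06 and 1.04 (adjusted p = 0.217 and 0.282). The mean of the oxidation list was 10.53 on induced replicate 3 against 8.89 and 8.91 on the other induced arrays, and that of the respiratory list 10.95 against 9.76 and 9.89. In the brown and beige adipocyte list Cidea alone rose of 14 genes, and the list did not shift by camera (median 0.48, adjusted p = 0.156). Its mean too was highest on induced replicate 3, at 6.64 against 5.97 and 5.97 on the other induced arrays and 5.71, 5.37 and 5.42 in control. Cidea is a lipid droplet protein that white adipocytes of some species also express. The cholesterol synthesis list did not shift (median 0.21, adjusted p = 0.678), 0 of 19 genes passing. Insig1 stood at 1.06 (adjusted p = 0.164) and Dhcr7 at 0.70 (adjusted p = 0.174).

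Cell division genes were lower. All 23 measured mitosis genes had negative estimates, median -1.18. Of these 1 fell over all genes, Kif23, a kinesin of cytokinesis, by 1.28 (SE 0.18, adjusted p = 0.0424), and 22 fell adjusted over the list alone (camera adjusted p = 3.81e-16, and adjusted p = 0.435 with an estimated correlation). The list mean was 9.08 ± 0.33 in control and 7.94 ± 0.43 in induced cells (SD, n = 3). All 22 genes of S phase and DNA replication had negative estimates too, median -0.65. None passed over all genes (0 of 22) and 8 fell adjusted over the list alone (camera adjusted p = 2.94e-08, and adjusted p = 0.435 with an estimated correlation). Rrm2 stood at -1.08 (adjusted p = 0.217) and Gins1 at -0.97 (adjusted p = 0.106).

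**Figure D2:**
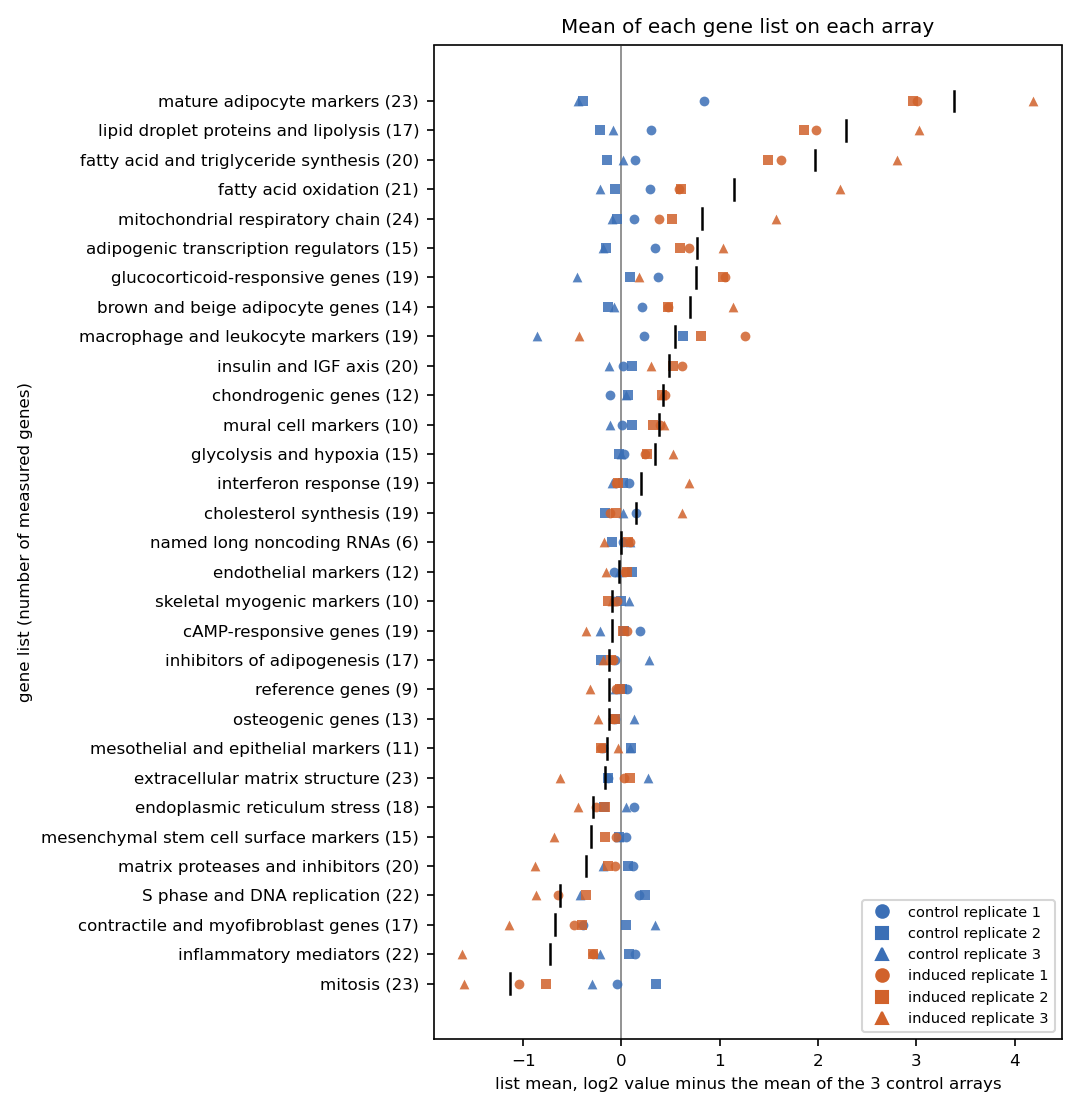
Mean of each of the 31 gene lists on each array, as the log2 value minus the mean of the 3 control arrays (horizontal axis), with the number of measured genes in brackets, 1 point per array and the induced mean as a black bar. Mature adipocyte markers lie highest and mitosis genes lowest, and induced replicate 3 lies apart from the other induced arrays in many lists.

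The contractile and myofibroblast genes were lower, 17 of 17 with negative estimates and a median of -0.62 (camera adjusted p = 1.48e-05, and adjusted p = 0.435 with an estimated correlation). Itga11 was the 1 gene that fell, by either adjustment. The mean was 8.51 on induced replicate 3 and 9.17 and 9.26 on the other induced arrays, against 9.27, 9.70 and 10.00 in control. Extracellular matrix genes as a list did not shift (median -0.40, adjusted p = 0.346). Of 23, Col4a2, a basement membrane collagen, rose by 1.08 (SE 0.12, adjusted p = 0.0243), and 4 rose adjusted over the list alone. Matrix proteases and their inhibitors missed the threshold (median -0.42, adjusted p = 0.0598), with 0 of 20 passing and 1, Timp4, rising adjusted over the list alone. Mmp12, a macrophage elastase, stood at -2.78 (adjusted p = 0.248) and Timp4 at 1.93 (adjusted p = 0.0564). Mmp12 read 9.07 and 8.59 on control replicates 1 and 2 and 4.81 on control replicate 3. Mesenchymal stem cell surface markers were lower by camera (median -0.40, adjusted p = 0.048, and adjusted p = 0.439 with an estimated correlation), with 0 of 15 passing and 2 falling adjusted over the list alone. Their 2 largest estimates pointed apart, Mcam at 2.42 (adjusted p = 0.191) and Cd34 at -1.31 (adjusted p = 0.269). That call was lost without control replicate 1 (adjusted p = 0.105), induced replicate 2 (0.0531) or induced replicate 3 (0.691). The list mean was 7.57 on induced replicate 3 and 8.20 and 8.09 on the other induced arrays.

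Targets of the glucocorticoid receptor were higher, in cells whose medium held dexamethasone. Of 19 genes 3 rose, 5 adjusted over the list alone: Tsc22d3, a glucocorticoid-induced leucine zipper, by 2.31 (SE 0.21, adjusted p = 0.0154), Fkbp5, a co-chaperone of the receptor, by 1.52 (SE 0.20, adjusted p = 0.033), and Ddit4, an inhibitor of mTORC1, by 1.25 (SE 0.17, adjusted p = 0.0371). The list median was 0.56 (camera adjusted p = 1.56e-05, and adjusted p = 0.435 with an estimated correlation). The cAMP-responsive list did not shift (median -0.19, adjusted p = 0.678), with 0 of 19 passing. Nr4a1, an immediate early gene, stood at -2.56 (adjusted p = 0.152) and the phosphodiesterase Pde3b at 2.20 (adjusted p = 0.162). The insulin and IGF axis was higher by camera (median 0.31, adjusted p = 0.0401, and adjusted p = 0.435 with an estimated correlation). In it 0 of 20 genes passed, while 5 rose and 1 fell adjusted over the list alone. Slc2a4, the insulin-regulated glucose transporter, stood at 3.07 (adjusted p = 0.067) and Igfbp5 at 2.13 (adjusted p = 0.46). The call was lost without control replicate 1 (adjusted p = 0.0653), induced replicate 1 (0.13) or induced replicate 2 (0.0659). Glycolysis and hypoxia genes were higher by camera (median 0.43, adjusted p = 0.048, and adjusted p = 0.435 with an estimated correlation), with 0 of 15 passing and 2 rising adjusted over the list alone. Pfkfb3 stood at 1.71 (adjusted p = 0.0866) and Pdk1 at 1.28 (adjusted p = 0.248). That call was lost without control replicate 1 (adjusted p = 0.146), control replicate 2 (0.0735) or induced replicate 2 (0.072).

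Inflammatory mediators were lower (median -0.75, camera adjusted p = 0.00534, and adjusted p = 0.435 with an estimated correlation). Of 22, only Il1a, which encodes interleukin 1 alpha, fell over all genes, by 1.76 (SE 0.21, adjusted p = 0.0266), and 4 fell adjusted over the list alone. The list mean was 6.79 on induced replicate 3 and 8.12 and 8.11 on the other induced arrays, and without that array the call was lost (adjusted p = 0.0764). Endoplasmic reticulum stress genes were lower by camera (median -0.38, adjusted p = 0.00609, and adjusted p = 0.477 with an estimated correlation), with 0 of 18 passing and 1 falling adjusted over the list alone. Their mean was 9.81, 9.50 and 9.72 on control replicates 1 to 3 and 9.42, 9.51 and 9.23 on induced ones, so the groups overlapped. Trib3 stood at -0.71 (adjusted p = 0.603) and Creld2 at -0.70 (adjusted p = 0.201). Without control replicate 1 the adjusted p was 0.0748. The interferon list was higher by camera (median 0.31, adjusted p = 0.0421, and adjusted p = 0.64 with an estimated correlation), with 0 of 19 passing by either adjustment. Ifit2 stood at -0.86 (adjusted p = 0.143), against the direction of its list, and Irf1 at 0.73 (adjusted p = 0.252). The list mean was 6.88 on induced replicate 3 and 6.13 and 6.15 on the other induced arrays, against 6.26, 6.20 and 6.09 in control, and the call was lost without that array (adjusted p = 0.852), control replicate 2 (0.0587) or control replicate 3 (0.139).

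Markers of other cell types were measured as well. Macrophage and leukocyte markers were higher by camera (median 0.49, adjusted p = 0.0266, and adjusted p = 0.631 with an estimated correlation), with 0 of 19 passing by either adjustment. Their mean was low on the replicate 3 array of both groups: 6.47, 6.87 and 5.39 on control replicates 1 to 3, and 7.50, 7.06 and 5.81 on induced replicates 1 to 3. The complement gene C1qb stood at 1.89 (adjusted p = 0.282) and read 8.17 and 7.60 on induced replicates 1 and 2 against 4.92 to 5.09 on all other arrays. Cd68 stood at 1.39 (adjusted p = 0.347). Without control replicate 3 the list's adjusted p was 0.42, without induced replicate 1 it was 0.316 and without induced replicate 2 it was 0.0842. Other lists were also lowest on replicate 3 of both groups, among them the glucocorticoid, mitosis and S phase lists. The glucocorticoid mean was 9.41, 9.13 and 8.59 on control replicates 1 to 3 and 10.10, 10.08 and 9.22 on induced replicates 1 to 3.

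**Figure D3:**
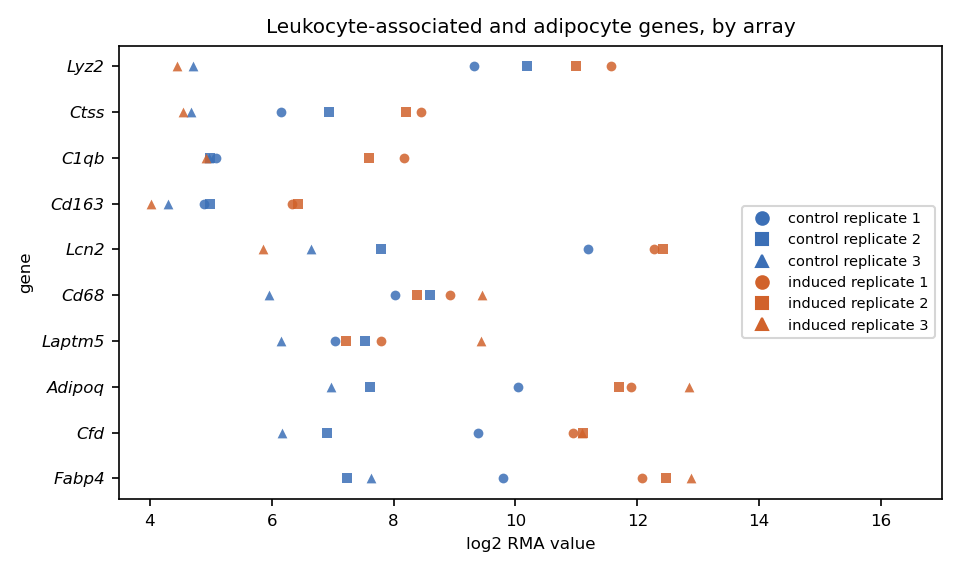
Log2 RMA value (horizontal axis) of 7 leukocyte-associated genes and 3 adipocyte genes, 1 point per array, chosen after the arrays were seen. Lyz2 reads 4.71 on control replicate 3 and 4.44 on induced replicate 3, against 9.31 to 11.56 on the other arrays, while Cd68 and Laptm5 read highest on induced replicate 3.

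No other lineage list shifted. The adjusted p was 0.665 for osteogenic genes (median -0.06), 0.346 for chondrogenic genes (median 0.01, mean 0.42), 0.972 for endothelial markers, 0.196 for mural cell markers (median 0.17), 0.665 for mesothelial and epithelial markers (median -0.03) and 0.665 for skeletal myogenic markers (median -0.05), and 0 of their genes passed over all genes. Adjusted over the list alone, 1 osteogenic gene fell, 2 chondrogenic genes and 1 mural gene rose, and 0 passed in the other lists. Endothelial markers had a median of 0.03 and a mean of -0.02, so their sign is not settled. The lubricin gene Prg4 stood at 3.48 (adjusted p = 0.0544) and Sox6 at 1.45 (adjusted p = 0.244) among chondrogenic genes. Runx2, the osteoblast regulator, stood at -1.22 (adjusted p = 0.0614) and Omd at -1.52 (adjusted p = 0.151). Steap4 stood at 1.04 (adjusted p = 0.598), Tek at -0.74 (adjusted p = 0.34), Egfl7 at 0.61 (adjusted p = 0.385), Msln at -1.17 (adjusted p = 0.26), Wt1 at -0.51 (adjusted p = 0.442), Des at -0.58 (adjusted p = 0.509) and Myog at -0.16 (adjusted p = 0.712). The 9 reference genes did not shift (median -0.19, adjusted p = 0.272). Among them B2m stood at 0.50 (adjusted p = 0.143) and Ywhaz at -0.33 (adjusted p = 0.366).

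Of 416 noncoding features, 1 changed by limma, and 29 had an unadjusted p under 0.05. It was the feature of the microRNA gene Mir126a, which rose by 4.67 (SE 0.52, adjusted p = 0.0373 over features), from 6.32 ± 0.27 to 10.98 ± 1.11 (SD, n = 3). The array labels total RNA, so the feature may not separate mature microRNA from its precursor. It is numbered 17770717, close to the feature of Agpat2 (17770719, a gene outside the naming rule). Agpat2 rose by 2.89 (limma adjusted p = 0.0145 over genes). Whether the Mir126a feature also reads RNA of Agpat2 was not tested, so the rise may not be that of the microRNA alone. Of 363 microRNA features 1 was called, and of 41 long noncoding RNA features 0. Only 6 of the 42 listed long noncoding RNAs were measured and the list did not shift (median 0.05, mean -0.01, adjusted p = 0.887). Meg3 stood at -0.45 (adjusted p = 0.585) and Snhg4 at 0.28 (adjusted p = 0.67). The one noncoding call was lost when control replicate 1, 2 or 3 or induced replicate 1 or 2 was left out (0 features), and 2 features were called without induced replicate 3 or without the 5087 low-numbered unnamed features.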

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

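The tests in this part use planned settings, except 3 settings chosen after the data were seen: leaving out both replicate 3 arrays, leaving out 5087 unnamed features numbered below the first named one, and an estimated correlation without induced replicate 3, which called 0 lists. Against 136 genes changed, a second quantile normalization gave 147 (132 shared), centring 130 (122), the dimmest 1 in 3 left out 152 (129), a trended and robust prior 124 (117) and averaged features 134 (134). Array weights gave 929 genes (474 higher, 455 lower, 136 shared), 458 at least 2-fold changed, 266 features and 2 noncoding features. The dimmest features left out gave 112 features and 2 noncoding ones, where fewer features were tested. A test against a 2-fold change called 8 genes. Without both replicate 3 arrays there were 740 genes (416 higher, 324 lower, 135 shared), 457 at least 2-fold changed, 149 features and 2 noncoding ones. Without the low-numbered unnamed features there were 124 features and 2 noncoding ones. Apart from fewer features tested, the cause was not tested.

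With 1 array left out, genes changed ranged from 2 to 557, genes changed at least 2-fold from 2 to 350, features from 2 to 216 and noncoding features from 0 to 2. List adjusted p ranged from 0.172 to 0.829 for inhibitors of adipogenesis, 0.19 to 0.841 for cholesterol synthesis, 0.107 to 0.863 for extracellular matrix, 0.42 to 0.996 for cAMP-responsive genes, 0.612 to 0.961 for endothelial markers and 0.612 to 0.964 for long noncoding RNAs, and the direction turned in each. It ranged from 0.0157 to 0.146 for glycolysis and hypoxia, 0.00437 to 0.691 for mesenchymal surface markers, 0.0142 to 0.852 for matrix proteases, 0.000771 to 0.13 for the insulin and IGF axis, 0.0015 to 0.0764 for inflammatory mediators, 0.00437 to 0.852 for interferon response, 0.00123 to 0.0748 for endoplasmic reticulum stress and 1.27e-06 to 0.42 for leukocyte markers. The lists of adipogenic regulators, mature adipocyte, synthesis, droplet, oxidation, respiratory chain, contractile, S phase, mitosis and glucocorticoid genes kept their call and direction with any 1 array left out. Meg3, at -0.45, stood at 0 without control replicate 3 (range -0.73 to 0). The 80 named genes include uncalled ones, which had no call to lose. Of the named genes 35 lost their call without induced replicate 1, 32 with the replicate block and 30 without control replicate 2. Another 28 did so without control replicate 3, 28 without induced replicate 2, 12 without control replicate 1 and 1 with centring. None of the called ones (0) turned direction under any setting. Of all 136 called genes, 2 kept their call without induced replicate 1 and 12 with the replicate block. The cause was not tested.

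With an estimated correlation the adjusted p of called lists was 0.435, except 0.439 for mesenchymal surface markers, 0.477 for endoplasmic reticulum stress, 0.631 for leukocyte markers and 0.64 for interferon response. With fry it was 0.0559 for mature adipocyte, synthesis, droplet, glycolysis and insulin lists, 0.0891 for mitosis, 0.112 for adipogenic regulators, 0.138 for glucocorticoid genes, 0.182 for S phase, 0.187 for contractile genes, 0.195 for respiratory chain, inflammatory and endoplasmic reticulum stress genes, 0.204 for oxidation, 0.269 for mesenchymal surface markers, 0.527 for interferon response and 0.53 for leukocyte markers, with endothelial markers (0.927) and long noncoding RNAs (0.972) turned. Mesenchymal surface markers lost their call under quantile normalization (0.0542), the dimmest genes left out (0.149), array weights (0.39) and both replicate 3 arrays left out (0.398). Interferon response lost it with the dimmest genes left out (0.149) and array weights (0.488), and turned without both replicate 3 arrays (0.656). The dimmest genes left out ended the calls of glycolysis (0.0754) and leukocyte markers (0.0536), and the trended prior that of glycolysis (0.0509). Uncalled lists turned under array weights (cholesterol synthesis 0.817, cAMP 0.886), averaged features (long noncoding RNAs 0.805) and without both replicate 3 arrays (inhibitors of adipogenesis 0.667, cholesterol synthesis 0.323, extracellular matrix 0.38, osteogenic genes 0.763). The cause was not tested.

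Replicate numbers are shared between the groups, but the labels do not say that they pair the cultures, so the main fit held no block. Deviations from the group means correlated at 0.023, 0.12 and 0.15 for equal numbers and at -0.14 to 0.12 for unequal ones. Control replicate 1 correlated better with induced replicate 2 (0.043). The mitosis mean was 9.03, 9.43 and 8.78 on control replicates 1 to 3. On induced replicates 1 to 3 it was 8.04, 8.31 and 7.48, the same order. Whether cultures of 1 number share an origin or a day is therefore not settled. With the replicate block, 12 genes changed (11 higher, 1 lower, 12 at least 2-fold), 5 features and 0 noncoding features. Matrix proteases were called (0.0416), interferon response was not (0.0688), and endothelial markers turned (0.954). With no detection calls, how far signals lie above background is not known.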

Other observations

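The patterns below were found in these data, and the tests of array-wide scaling, of fewer leukocytes in replicate 3 and of induced RNA in control replicate 1 were chosen after the result was seen. The genes named in this paragraph and the next were picked after their values were seen, and no group of genes was tested. Hp, which encodes haptoglobin, rose by 4.13 (SE 0.31, adjusted p = 0.00799), from 6.90 ± 0.49 to 11.03 ± 0.42 (SD, n = 3 arrays, limma). Orm1, the acid glycoprotein orosomucoid, rose by 3.96 (SE 0.50, adjusted p = 0.0323), and the terminal complement gene C6 by 3.64 (SE 0.26, adjusted p = 0.00799). Mrap, an accessory protein of melanocortin receptors, rose by 3.71 with a small spread (SE 0.15, adjusted p = 0.000952), and the peroxidase gene Lpo by 3.95 (SE 0.35, adjusted p = 0.0144). In all of these the 3 induced arrays lay above the 3 control arrays.

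The feature of Mir126b passed at the gene level beside that of Mir126a, rising by 3.78 (SE 0.52, adjusted p = 0.0382), from 3.07 ± 0.44 to 6.85 ± 1.06 (SD, n = 3). Egfl7, known as the host gene of this microRNA, stood at 0.61 (SE 0.32, adjusted p = 0.385). The difference between host and microRNA was not tested.

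Leukocyte markers were lower on the replicate 3 array of both groups, where Lyz2 (outside the naming rule) read 4.71 and 4.44 against 9.31 to 11.56 on the others. Replicate 3 lay below the lower of replicates 1 and 2 in the list mean by 1.09 in control and 1.25 in induced cells. Scaling of whole arrays by 1 factor is argued against for these arrays, since it would move all genes of an array alike. Quantile normalization would then remove it, leaving neither these gaps nor lists moved in opposite directions. By over 2 standard errors, 4 of 30 other fixed lists in control and 7 of 30 in induced cells were higher on replicate 3 than on both other arrays. In induced cells fatty acid oxidation (1.62, SE 0.16), synthesis (1.18, SE 0.12) and respiratory chain genes (1.06, SE 0.06) lay far past that limit. In control the lists were contractile (0.30, SE 0.11), osteogenic (0.19, SE 0.08), extracellular matrix (0.41, SE 0.20) and inhibitors of adipogenesis (0.35, SE 0.16). The last 2 passed only narrowly. Normalization balances lower values with higher ones, so the number of such lists cannot by itself decide. It also fixes the median over all genes, on which a first test was dropped. What 1 factor forbids are the opposite moves on induced replicate 3. There the leukocyte list lay 1.25 lower and fatty acid oxidation 1.62 (SE 0.16) higher than on the other induced arrays. Leukocytes carried into the replicate 1 and 2 cultures may contribute. On a second leukocyte list of 50 genes, 43 measured and none shared with the first, replicate 3 lay at least 0.535 below the lower of the others in both groups. A gap of this size is not particular to leukocytes. The glucocorticoid list read 8.59 on control replicate 3 against 9.41 and 9.13, and 9.22 on induced replicate 3 against 10.10 and 10.08. The second list therefore cannot tell leukocytes from other sources. Cd68 (9.45) and Laptm5 (9.43, outside the naming rule) go against leukocytes, being highest on induced replicate 3. No explanation besides leukocytes and array-wide scaling was tested for this pattern.

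Induced replicate 3 stood apart from induced replicates 1 and 2 by over 2-fold in 1287 genes, 673 higher and 614 lower. On it Pdgfra read 9.05 against 11.99 and 11.95, and Ehhadh 9.77 against 6.68 and 6.77 (both outside the naming rule). Fewer leukocytes in replicate 3 are argued against as the whole cause, since control replicate 3 was shifted by a median of only 0.0263 of the shift in induced replicate 3. That holds only if leukocytes brought the same genes by like amounts in both groups. Lyz2 was low on replicate 3 of both groups, but C1qb was high on induced replicates 1 and 2 only. A further step along the direction already taken by induced replicates 1 and 2 is argued against for part of the genes only. Of the 1287 genes, 14.2% had moved the opposite way by at least 0.5 there. Another 30.2% had moved the same way by at least 0.5 (43.1% of the higher and 16.1% of the lower genes). The test counts a smaller move the same way against this cause, so it cannot decide for the remaining genes. A difference in culture or handling stays open.

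Adipocyte markers were higher on control replicate 1 than on the other control arrays, and induced RNA mixed into that sample may be a candidate source. A mixture would give all genes induced at least 8-fold 1 share, yet of 55 such genes outside the marker list 25.5% (14 genes, exact 95% interval 14.7 to 39.0%) gave at most 0.2 of the markers' median share of 8.36%. Shares within 2-fold of that median were given by 54.5% of them (interval 40.6 to 68.0%), short of the 75% that a mixture was said to need, and while 25.5% passes the bound of 25% set for excluding one, its interval, asked for only after the value was seen, does not, so the question is left open where the value alone would have excluded it. A second form of the test, with limits set after the values of single genes had been seen, pointed to exclusion and was dropped for that reason. Implied shares differed between genes, for example -0.999% for Agt, 0.537% for Pnpla3, 20.5% for Adipoq and 28.4% for Cfd (chosen after the values were seen), and adipocytes forming in that culture stay open and untested.

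Splits of the 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 with the largest value throughout: 69 features against at most 0 in other splits, 136 genes against 0, 114 genes changed at least 2-fold against 0, 1 noncoding feature against 0, and 17 gene lists called by camera against 16. Every other split put arrays of both groups on each side, so the group difference added to its spread. Few single-gene calls could come of such splits, and their 0 counts are no measure of chance. For gene lists, other splits called 3 to 16, so the number of camera calls hardly sets the real split apart.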
